A study of Homo sapiens with 8 samples.

How the data were processed

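Single-nucleus RNA-seq of 8 frozen quadriceps biopsies was used, 4 libraries labelled non-injured and 4 labelled injured. Per the labels' protocols, nuclei were sorted by their DNA stain and made into libraries with a droplet kit that reads the 3' ends of transcripts. The deposited values are counts of unique molecules (UMIs) per gene and barcode, made with Cell Ranger 6.0.0 on GRCh38 per the submitters' processing notes, and the other deposited files hold the barcodes and the gene IDs with their symbols. Whether reads in introns or on the other strand were counted, and the annotation release, are not given in the sources used here. The tables had 36601 genes, the same in every library, and 34616 of their IDs were in the GENCODE annotation held, release 29, from which coordinates were taken. A fixed set of 113 genes linked to sex was left out throughout.

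The libraries held 29703 barcodes, 2848 to 5026 each, and 3840022 to 27699706 UMIs each. Nuclei with at least 300 genes and at most 5% mitochondrial counts were kept, which left 26369. Doublet scores came from Scrublet as built into scanpy 1.11.5. Its automatic threshold found 13 nuclei, so the highest scores were removed at an assumed rate of 0.8% per 1000 barcodes, which took out 823 and left 25546 nuclei, 1872 to 4693 per library, with a median of 616 to 1839 genes. This choice was made after the data were examined. Libraries were integrated and clustered with Seurat 5.3.0 on 2000 variable genes and 30 principal components at resolution 0.5.

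Clusters were named from 20 fixed marker sets. The thresholds of the naming rule, a score of 3 on the log2 scale, a type I minus type II score of at least 1 or at most -1.5, and detection in 10% of nuclei with a pseudocount of 5 CPM, were set after the clusters were seen. Type II myonuclei were clusters 0, 1 and 3, type I myonuclei clusters 2 and 5, fibro-adipogenic nuclei cluster 4, endothelial nuclei cluster 7, mural nuclei cluster 8, satellite cell nuclei cluster 9, macrophages cluster 10 and T and natural killer cells cluster 12. Clusters 13, 14 and 15 held 72 adipocyte, 36 B cell and 34 mast cell nuclei. Clusters 6 and 11 were myonuclei of no assigned type, with 1366 and 287 nuclei, and counted only in the pooled myonuclei. Among the leading genes of cluster 3 were 3 haemoglobin genes, and fibre results were also computed without clusters 3 and 5, which were rich in haemoglobin transcripts.

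Counts were summed per library and class where a library had at least 20 nuclei of the class. Changes were fitted with edgeR 4.0.16 on R 4.3.3, as a quasi-likelihood model with TMM scaling, its expression filter, and the replicate number as a block. P-values were two-sided and adjusted by Benjamini-Hochberg at 0.05. CPM are counts scaled to the class sum of a library after TMM adjustment, except for free RNA, single clusters and where stated, for which the plain sum was used. Each log2 change is injured minus non-injured, with the standard error (SE) that the F statistic implies. The numbers pair the libraries because library names share a number between groups. As a check, libraries of the same number deviated together: their correlations across genes ran from 0.297 to 0.585 in type II nuclei, where the highest between other numbers was 0.271, and from 0.320 to 0.607 in all myonuclei, where it was 0.279. It was less clear in other classes: each of the 3 non-injured libraries correlated best with its own number in endothelial nuclei, but 2 of 4 did in type I, 2 of 4 in fibro-adipogenic and 2 of 3 in satellite cell nuclei. With no replicate block, the type II count was 817 genes.

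Gene lists, 38 in number, were fixed before the data were examined, as were the design, the alternatives and the rule for genes named in the text, and lists with at least 4 tested members were tested. Camera of limma 3.58.1 used its preset correlation of 0.01 and, as an alternative, the correlation estimated from the data; fry tested whether the genes of a list move to 1 side. The difference between type I and type II changes was tested as an interaction with each library as a block. Shares of nuclei and quality measures were compared with the exact two-sided permutation test over 70 splits, adjusted over the family, and with an exact sign-flip test over pairs. Confidence intervals of single-library shares are exact (Clopper-Pearson, 95%), and a count of 0 is given an upper limit of 3 counts of the library's total; both cover counting error only.

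Genes were named by a rule. In type I and type II myonuclei these were the 12 largest rises and 12 largest falls past the threshold, elsewhere 5 and 5. They had to move the same way in every pair and have a mean of at least 10 CPM. Clone names, Ensembl IDs and names of the LINC series were left out. Added to these were 20 fixed fibre genes, such as CHRNA1, RUNX1, MYH2 and FBXO32, and up to 4 members of each list with the smallest adjusted p. In the report, genes outside the rule are said to be chosen after their values were seen. The result of 1 gene that the rule names is not reported here.

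The free RNA fraction of a class was the median ratio of 20 myofibre transcripts in that class to the myonuclei of the same library. Each model was tested on simulated counts with 200 changed genes. At a log2 change of 1 and of 2 the fits recovered 44.3% and 98.9% of them in type II nuclei, 20.2% and 95.5% in type I nuclei, 39.6% and 88.2% in all myonuclei, 18.5% and 91.5% in fibro-adipogenic nuclei, 5.7% and 73.5% in endothelial nuclei, and 29.5% and 90.8% in satellite cell nuclei; the interaction recovered 2% and 26%. The share of false calls was at most 4.76%. These counts were drawn gene by gene from the kind of model that was fitted, with the same change in every pair. The rates are therefore not those of the real data, where genes are not independent and pairs can differ in their response.

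Alternatives were DESeq2 1.42.0, DESeq2's size factors in edgeR, no low-count filter, no replicate block, each replicate left out, each batch alone, class sums thinned to equal totals, a stricter filter of 500 genes and 2% mitochondrial counts, doublets kept, no integration, and resolution 1.0. Clustering without the called genes, leaving out haemoglobin-rich clusters and the larger fibro-adipogenic cluster alone were added after the data were examined. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest. Reads were not used here.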

Results

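Single-nucleus RNA-seq was read from 8 biopsies of the quadriceps, the thigh muscle that extends the knee, taken around reconstruction of the anterior cruciate ligament of the knee. The labels call 4 libraries non-injured and 4 injured, numbered 1 to 4 in each group. The series description places the biopsies before and after surgery, and the protocol gives 7 days after surgery, but no label says which library was taken when or from which limb. Each difference below is therefore the library labelled injured minus the one labelled non-injured. The description also speaks of 2 individuals, while the library names carry 4 numbers, so the p-values measure the spread between 4 numbered pairs and may be too small if pairs share a person. Total counts of unique molecules (UMIs) were 13931062, 27699706, 9502021 and 3840022 in non-injured libraries 1 to 4. They were 11895082, 4993729, 11872244 and 4568011 in injured libraries 1 to 4. The filters and doublet removal kept 1872 to 4693 nuclei per library, with a median of 882.5 to 4235 UMIs per nucleus. Libraries 1 and 2 differ from libraries 3 and 4 of both groups in the molecule named on the label, so values are also given within each of these batches. Nuclei kept were 3428 ± 1171 (SD, n = 4) in non-injured and 2959 ± 545 (SD, n = 4) in injured libraries. For this count the exact two-sided permutation test gave p = 0.543. None of the 6 quality measures passed the adjusted threshold. That shows little, since the exact two-sided permutation test with 4 against 4 libraries cannot go below p = 0.0286 before adjustment. Adjustment over 6 measures can hardly leave that under 0.05, so a difference in quality between the groups stays possible.

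The first comparison asked which nuclei the biopsies held. Type I myonuclei, the nuclei of slow fibres that carry MYH7, were 14.8% ± 3.91 (SD, n = 4) of nuclei in non-injured and 28.7% ± 8.46 (SD, n = 4) in injured libraries, and were higher in 4 of 4 pairs. Type II myonuclei, the nuclei of fast fibres that carry MYH1 and MYH2, were 56.3% ± 13.7 (SD, n = 4) and 51.5% ± 8.12 (SD, n = 4). Macrophage nuclei, from the immune cells that clear debris, were 1.56% ± 0.293 (SD, n = 4) and 0.593% ± 0.203 (SD, n = 4), and were lower in 4 of 4 pairs. Fibro-adipogenic nuclei, from the connective tissue progenitors of muscle, were 9.15% ± 4.13 (SD, n = 4) and 5.66% ± 3.96 (SD, n = 4). No share passed the adjusted threshold. The type I share gave an exact two-sided permutation p = 0.0571 (adjusted p = 0.257), the macrophage share p = 0.0286 (adjusted p = 0.257), which is the smallest p that 4 against 4 libraries allow, and the type II share p = 0.629. A paired sign-flip test cannot go below 0.125 with 4 pairs, and the type I share reached that value. Within the batches, the type I share went from 19.2% and 9.91% to 36.7% and 33.8% in libraries 1 and 2, and from 13.8% and 16.1% to 26.4% and 17.7% in libraries 3 and 4. Endothelial nuclei of the vessel lining were 3.37% and 3.38% of nuclei, satellite cell nuclei of the muscle stem cells 2.65% and 2.88%, and T and natural killer cell nuclei 1.14% and 0.867%. Mural nuclei, from the cells around small vessels, were 2.48% ± 2.89 (SD, n = 4) and 3.90% ± 0.913 (SD, n = 4), with 0 of 1872 nuclei in non-injured library 4, which allows a share of up to 0.160%. Among fibre nuclei assigned to a type, type I made up 20.9% ± 4.50 (SD, n = 4) and 35.7% ± 10.1 (SD, n = 4) (exact two-sided permutation test, p = 0.0571). Since genes that define the classes changed, nuclei were also clustered without the genes called as changed, a choice made after the data were examined. The type I share was then 13.3% ± 3.12 (SD, n = 4) and 25.3% ± 6.51 (SD, n = 4) and the macrophage share 1.52% and 0.526%, each with an exact permutation p = 0.0286 and an adjusted p = 0.129. Among typed fibre nuclei, type I made up 21.2% and 34.4% (exact permutation p = 0.0857). This clustering put 523 nuclei of the main type I class and 1349 of type II into a mixed class. Its clusters were named from the same marker sets, so changed marker genes could still affect the names. Without integration of the libraries the type I share was higher by 7.65 percentage points (exact permutation p = 0.4), with 6 nuclei of injured library 2 assigned to type I against 809 in the main clustering. In the main clustering, cluster 2 held 73.8% and 72.7% of type I nuclei in the non-injured and injured libraries, and cluster 0 held 46.9% and 41.9% of type II nuclei.

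**Figure D1:**
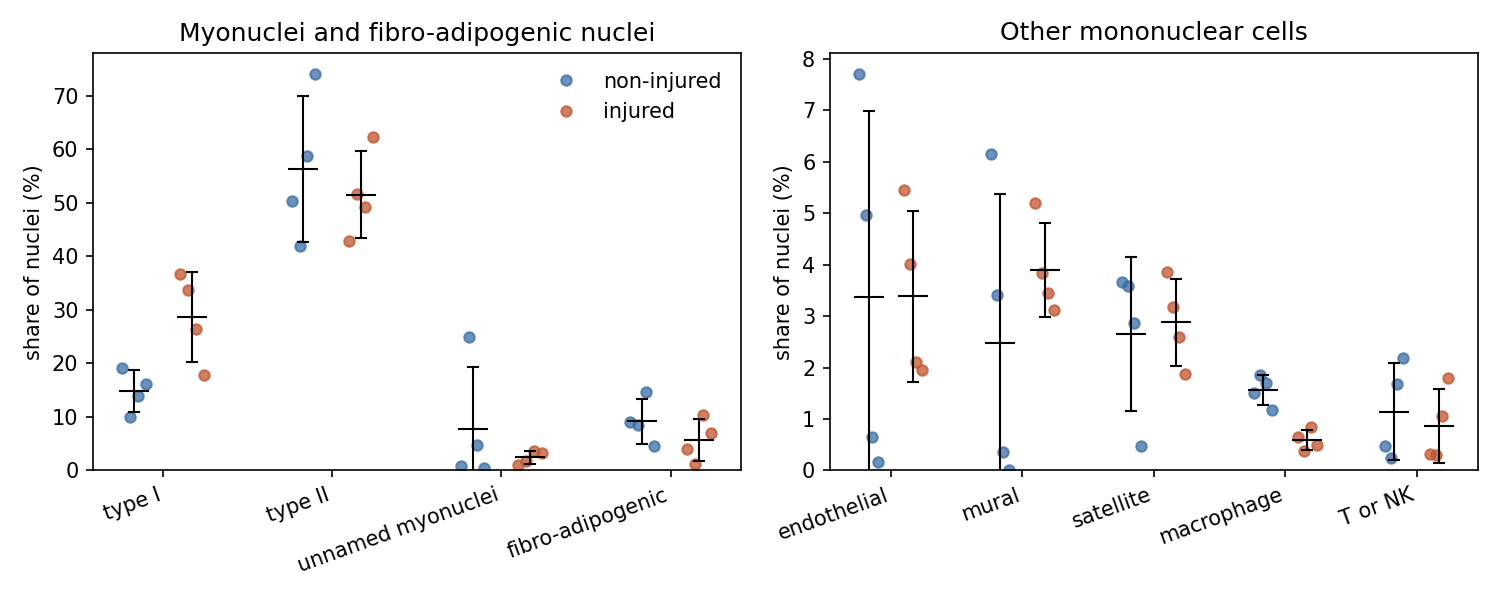
Percent of nuclei per class in each library, with non-injured and injured libraries side by side; points are libraries, black bars are means and error bars are SD (n = 4), drawn down to 0 at most. The type I mean was 14.8% in non-injured and 28.7% in injured libraries, and the macrophage mean 1.56% and 0.593%.

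The main comparison asked which transcripts changed in type II myonuclei. RUNX1 (ENSG00000159216, GRCh38 chromosome 21, 34787801 to 36004667), a transcription factor that fibres raise after loss of nerve supply, rose from 94.9 ± 62.5 to 1912 ± 654 CPM (counts scaled to the TMM-adjusted total of the class; SD, n = 4), a log2 change of 4.50 (SE 0.278, adjusted p = 0.000137). CHRNA1 (ENSG00000138435, chromosome 2, 174747592 to 174787935), the alpha subunit of the acetylcholine receptor, rose from 14.3 ± 19.8 to 293 ± 73.5 CPM, a log2 change of 5.14 (SE 0.771, adjusted p = 0.0037). ANKRD1 (ENSG00000148677, chromosome 10, 90912096 to 90921276), a stretch-responsive protein of the sarcomere, rose from 23.5 ± 30.6 to 921 ± 330 CPM, a log2 change of 5.91 (SE 0.465, adjusted p = 0.000383). ACTN3 (ENSG00000248746, chromosome 11, 66546395 to 66563329), the alpha-actinin of fast fibres, fell from 359 ± 251 to 4.07 ± 4.75 CPM, a log2 change of -6.47 (SE 0.678, adjusted p = 0.000932). HDAC9 (ENSG00000048052, chromosome 7, 18086949 to 19002416), a histone deacetylase that represses activity-dependent genes, fell from 387 ± 82.3 to 16.8 ± 11.9 CPM, a log2 change of -4.82 (SE 0.42, adjusted p = 0.000472). In all, 1415 of 12444 genes tested changed, 559 up and 856 down, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Leaving out replicate 1, 2, 3 or 4 gave 1016, 1021, 1124 and 732 genes, and no replicate block 817. The other largest rises among genes that moved the same way in 4 of 4 pairs were MIR503HG at 6.51, PNPLA3 (a lipase of lipid droplets) at 5.65, MYBPH (a myosin-binding protein) at 3.60, TGFB3 at 3.26, STS at 3.25, DPP6 at 3.24, GDNF (a growth factor for motor neurons) at 3.24, GXYLT2 at 3.23 and CFAP61 at 3.13 on the log2 scale. The other largest falls were NREP at -5.43, ASB18 at -4.86, PDE4C at -4.64, DHRS7C (an enzyme of the sarcoplasmic reticulum) at -4.61, GADL1 at -4.61, SLIT3 at -4.40, ATP2B2 at -4.30, RNF150 at -4.23, SMTNL1 at -4.21 and FRAS1 at -4.20. Libraries 1 and 2 alone and libraries 3 and 4 alone called 305 and 523 genes up and shared 165, against 13.5 expected of independent lists. They called 689 and 725 genes down and shared 392, against 42.3. The counting of strand and of introns was not given in the sources used here, and 38 of the 106 genes looked up overlap another gene on their strand and 69 on the other strand, so that values of such genes are uncertain.

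Genes fixed for type II myonuclei before the data were examined showed a mixed response. The acetylcholine receptor subunit CHRND rose (log2 2.63, SE 0.41, adjusted p = 0.00449), while the fetal subunit CHRNG was higher by 2.65 and did not pass (adjusted p = 0.179). MYOG (ENSG00000122180, chromosome 1, 203083132 to 203086036), the myogenic factor that drives receptor genes, rose by 1.89 from 36.7 to 133 CPM (adjusted p = 0.000956). GADD45A, a stress gene of denervated fibres, rose by 2.48 (adjusted p = 0.00477), whereas the atrophy ubiquitin ligases FBXO32 at 0.28 (adjusted p = 0.46) and TRIM63 at -0.73 (adjusted p = 0.0808) did not pass. MYH2 (ENSG00000125414, chromosome 17, 10521148 to 10549957), the myosin of type IIa fibres, changed by -1.41 from 3940 to 1604 CPM (adjusted p = 0.00817), and MYH7 changed by -1.61 (adjusted p = 0.00608). Over all libraries, MYH7 was at 43.1 CPM in type II cluster 0 and 720 in cluster 3, against 1175 and 1872 in type I clusters 2 and 5. Free RNA of type I fibres and the mix of type II clusters were not separated from the MYH7 change. MUSK (a receptor kinase of the synapse) at 0.90, NCAM1 (an adhesion molecule) at -0.33, MYH3 (embryonic myosin) at -0.06, MYH1 at -0.66, PPARGC1A (a regulator of mitochondria) at -0.56, PDK4 (a brake on glucose oxidation) at -1.02, DMD (dystrophin) at -0.10 and COL19A1 (a fibre collagen) at 2.41 did not pass. MYH8 and CDKN1A had too few counts to be tested. Adjusted p-values of those that did not pass ran from 0.0622 for COL19A1 upward.

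**Figure D2:**
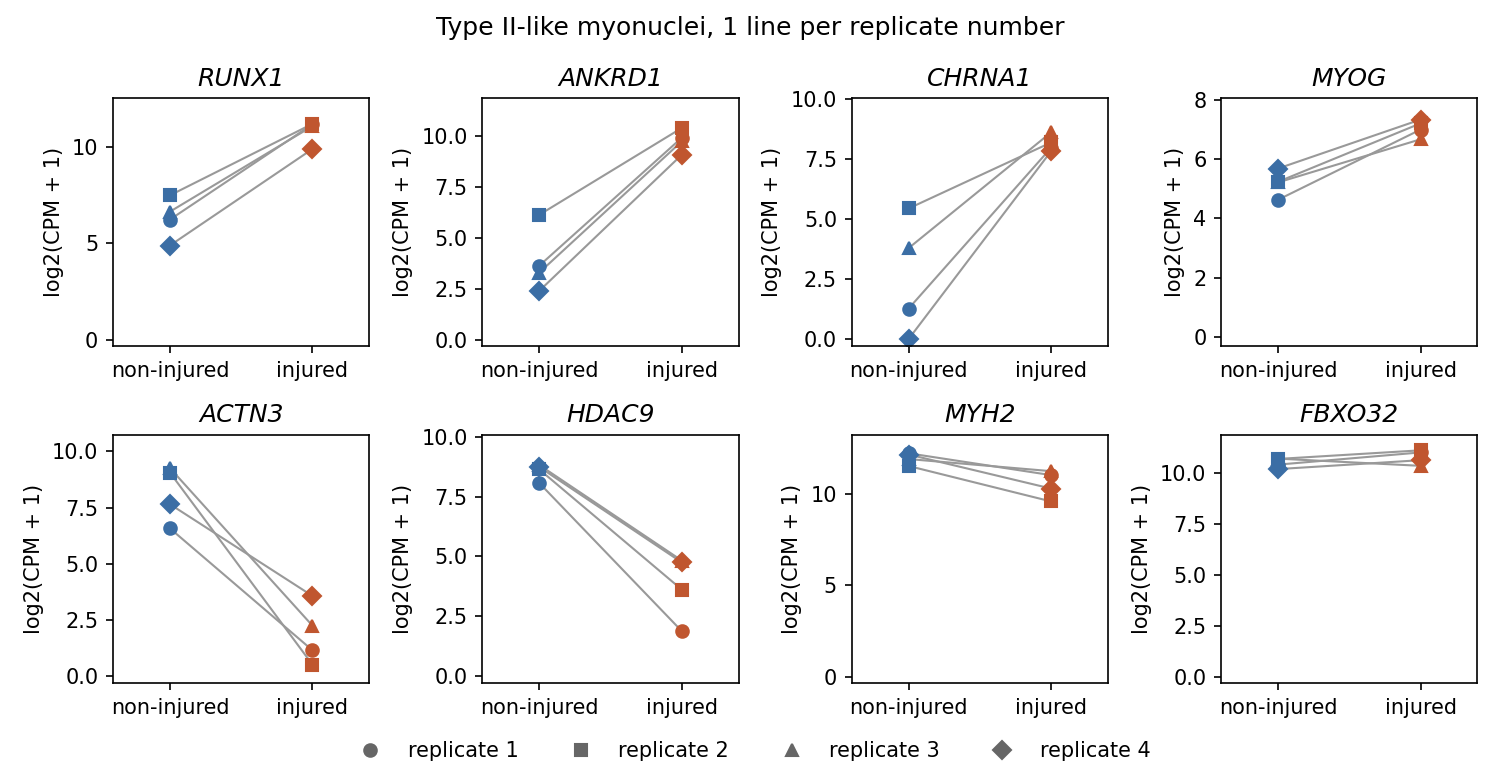
log2(CPM + 1) of RUNX1, ANKRD1, CHRNA1, MYOG, ACTN3, HDAC9, MYH2 and FBXO32 in type II myonuclei; each point is a library and each line joins libraries of the same number (n = 4 pairs). RUNX1 rose by 4.50 and ACTN3 changed by -6.47 on the log2 scale, while FBXO32 at 0.28 did not pass the test.

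Gene lists fixed beforehand were then read in type II myonuclei. Genes of the denervation response, a list tied to loss of the nerve, rose in 9 of 21 members, while 2 fell and 10 did not pass (11 up and 2 down adjusted over the list alone). The list set no direction for single members, so a fall need not speak against the response. RUNX1, ANKRD1, CHRNA1 and MYOG were among those that rose, and HDAC9 was among those that fell. The median was 1.03 and limma's camera gave an adjusted p = 2.24e-05, which was adjusted p = 0.494 with an estimated correlation. Genes of the fast sarcomere, the contractile proteins of fast fibres, fell in 10 of 15 members and in 13 when adjusted over the list alone, with TPM1 at -1.95, ATP2A1 (the calcium pump of fast fibres) at -2.93 and MYLK2 at -2.17. The median was -1.37, and camera's adjusted p = 6.58e-09 became adjusted p = 0.494 with an estimated correlation. Structural genes of the sarcomere and cytoskeleton fell in 15 of 26 members with none up (1 up and 18 down adjusted over the list alone), with ACTA1 at -2.87, MYOM1 at -2.31 and TCAP at -3.15. The median was -1.02, with adjusted p = 2.32e-08 and adjusted p = 0.478 with an estimated correlation. Excitation-contraction and calcium handling genes fell in 11 of 23 members (also 11 adjusted over the list alone), with JPH2 (a membrane tether) at -2.05 and CLCN1 (the chloride channel) at -1.64. The median was -0.79, with adjusted p = 1.84e-07 and adjusted p = 0.478 with an estimated correlation. Slow sarcomere genes fell in 3 of 11 members (5 adjusted over the list alone), with TNNI1 at -1.80 and a median of -1.10 (adjusted p = 0.00305, and adjusted p = 0.543 with an estimated correlation). Free RNA of type I fibres was not separated from these slow sarcomere values. Genes of the dystrophin complex fell in 7 of 18 members and rose in 1 (the same counts adjusted over the list alone), with TLN2 at -2.18 and DTNA at -1.52 and a median of -0.44 (adjusted p = 0.0327, and adjusted p = 0.543 with an estimated correlation).

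Lists of metabolism and the other lists that passed in type II myonuclei followed. Genes of glycolysis and glycogen fell in 14 of 26 members and rose in 1 (17 down and 1 up adjusted over the list alone), with ENO3 (muscle enolase) at -2.70, PGAM2 at -3.03 and LDHA at -1.61. The median was -1.04, with adjusted p = 3.98e-07 and adjusted p = 0.478 with an estimated correlation. Fatty acid genes fell in 6 of 24 members and rose in 1 (the same adjusted over the list alone), with FABP3 at -1.84 and CPT1B at -1.27. The median was -0.39, with adjusted p = 0.00748 and adjusted p = 0.478 with an estimated correlation. Of 76 oxidative phosphorylation genes 7 fell and 69 did not pass (also 7 adjusted over the list alone), with COX6A2 at -1.71. The median was -0.35, with adjusted p = 7.2e-06 and adjusted p = 0.543 with an estimated correlation. Clock genes fell in 7 of 17 members and rose in 2 (12 and 3 adjusted over the list alone), with BHLHE41 at -2.26 and PER3 at -1.57. The median was -0.87, with adjusted p = 0.00103 and adjusted p = 0.543 with an estimated correlation. Extracellular matrix genes fell in 7 of 24 members (10 down and 2 up adjusted over the list alone), with COL16A1 at -3.94 and a median of -0.75 (adjusted p = 0.00372, and adjusted p = 0.543 with an estimated correlation). Free RNA of fibro-adipogenic nuclei was not separated from these matrix values. The matrix gene TNXB went from 2502 to 588 CPM in fibro-adipogenic and from 18.8 to 2.79 in type II nuclei, scaled to the plain class total. Genes of inflammation and NF-kB rose in 1 member, TNFRSF12A at 2.68, and fell in 1, TNFAIP2 at -1.44, of 15 (3 up and 1 down adjusted over the list alone), with a median of 0.38 (adjusted p = 0.0327, and adjusted p = 0.478 with an estimated correlation). Myofibre transcripts, a set of abundant fibre genes, fell in 8 of 20 members (11 adjusted over the list alone) with a median of -0.73, CKM (creatine kinase) at -1.98, adjusted p = 7.92e-07, and adjusted p = 0.478 with an estimated correlation. No list in any class held its call with an estimated correlation. In simulated counts, without correlation between genes, 1 list was raised as a whole by 1 on the log2 scale. That form of camera then gave adjusted p = 0.0427 in type II nuclei, just past the threshold. It gave 0.042 in type I, 0.0886 in all myonuclei, 0.165 in fibro-adipogenic, 0.196 in satellite cell and 0.379 in endothelial nuclei. The lack of calls therefore does not decide against changes of the lists. A rotation test of the same lists (limma's fry), which asks whether the genes of a list move 1 way on balance, called 11 of 35 lists in type II myonuclei with a lowest adjusted p = 0.0375.

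Other lists did not pass camera's test in type II myonuclei. Neuromuscular junction genes rose in 4 and fell in 1 of 18 members, and the same adjusted over the list alone, with PRKAR1A (a kinase subunit) at 2.58 among those that rose and COLQ, the anchor of acetylcholinesterase, the 1 that fell (adjusted p = 0.317). Atrophy ligases and FOXO genes rose in 2 and fell in 1 of 22 members (2 and 2 adjusted over the list alone), with CBLB at 1.02 and FBXO40 at -2.13 (adjusted p = 0.616). None of 33 proteasome subunits changed, also adjusted over the list alone (adjusted p = 0.0751). Autophagy genes rose in 3 and fell in 2 of 24 members (the same adjusted over the list alone), with CTSD (a lysosomal protease) at 1.27 and WIPI1 at -0.93 (adjusted p = 0.635). Growth arrest genes of the p53 response rose in 4 and fell in 2 of 14 members (5 and 2 adjusted over the list alone), with BBC3 at 2.69, MDM2 at 1.26 and GADD45G at -3.12 (adjusted p = 0.111). Glucocorticoid-responsive genes rose in 2 and fell in 3 of 19 members (2 and 8 adjusted over the list alone), with SGK1 at -2.30 and GLUL at -2.42 (adjusted p = 0.055). Regulators of mitochondria fell in 3 of 13 members (also 3 adjusted over the list alone), with ESRRG at -1.88 and PERM1 at -2.26 (adjusted p = 0.104). TGF-beta response genes rose in 3 of 16 members (4 up and 3 down adjusted over the list alone), with TGFB3 at 3.26 and CCN1 at 2.34. The median was -0.02 while the mean of 0.16 and the test pointed up (adjusted p = 0.653). Heat shock genes rose in 2 and fell in 1 of 19 members (3 and 1 adjusted over the list alone), with HSPH1 at 1.95 and HSPB2 at -1.92 (adjusted p = 0.317). The 13 lists left, among them interferon, hypoxia, unfolded protein, ribosomal and mitochondrially encoded genes, had adjusted p-values from 0.176 to 0.964. Signs differed in 3 of these: complement had a median of 0.01, a mean of -0.17 and a test pointing down, immediate early genes 0.07, -0.07 and up, and angiogenesis 0.19, -0.10 and down.

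**Figure D3:**
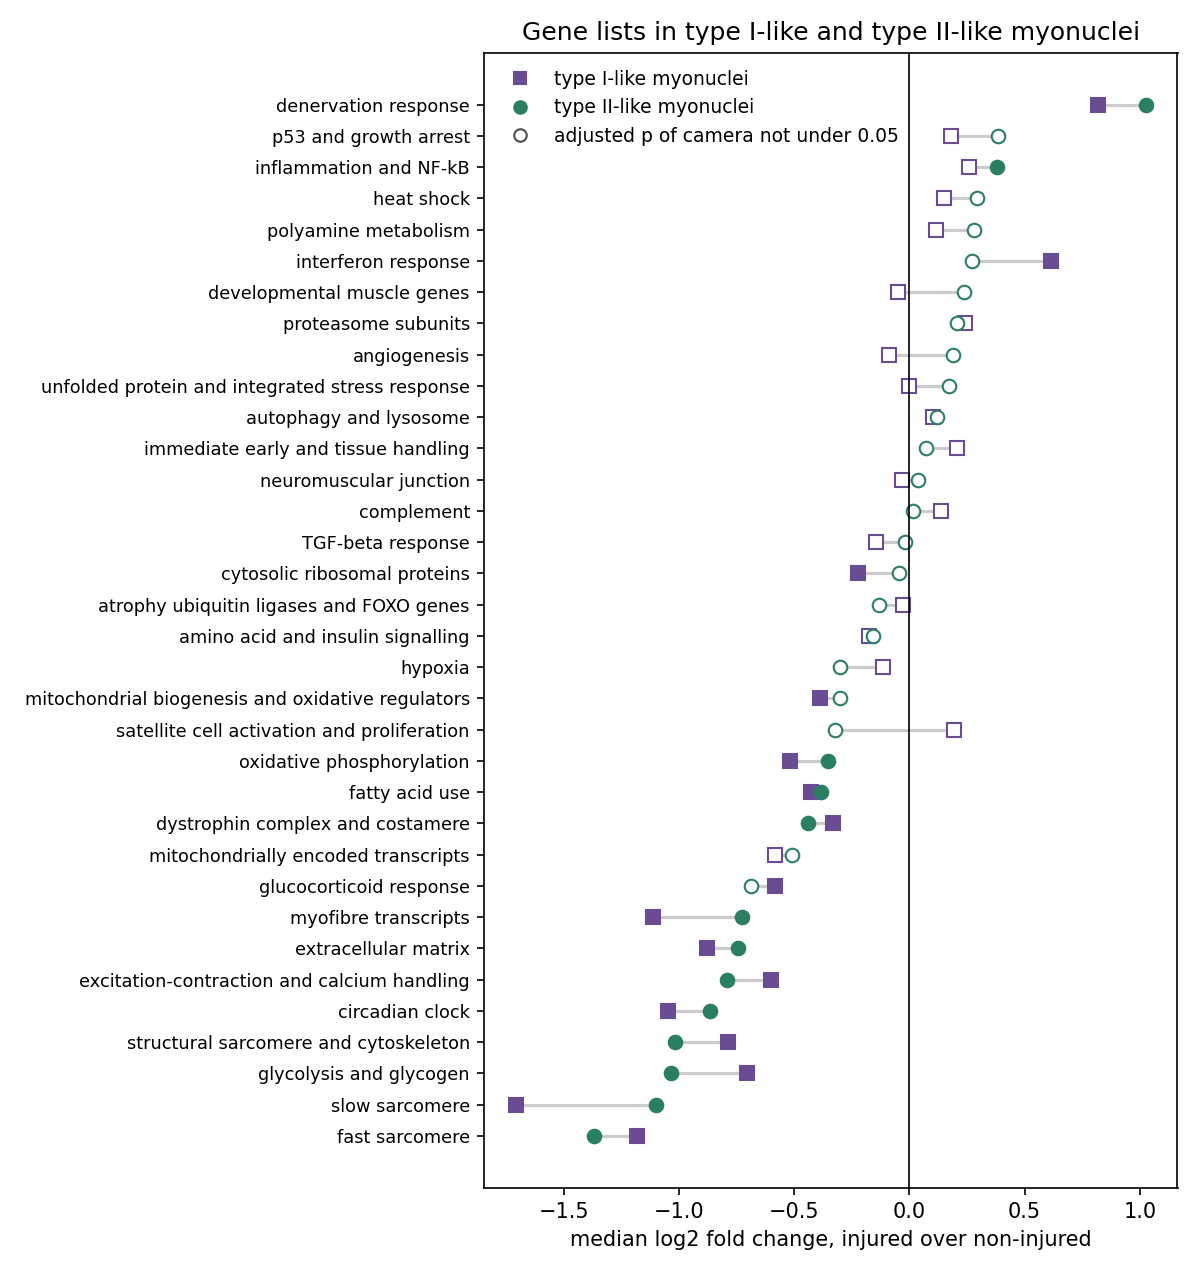
Median log2 change of the gene lists tested in both type I (squares) and type II (circles) myonuclei, filled where camera's adjusted p passed 0.05 with its preset correlation. The denervation response median was 0.82 in type I and 1.03 in type II nuclei, and the fast sarcomere median -1.18 and -1.37.

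The next comparison asked the same of type I myonuclei, the slow fibres. RUNX1 rose from 45.6 to 905 CPM, a log2 change of 4.20 (SE 0.36, adjusted p = 0.0136), in 4 of 4 pairs. CHRNA1 rose from 14.9 to 217 CPM, a log2 change of 3.80 (SE 0.49, adjusted p = 0.026), and CHRND by 3.06 (SE 0.46, adjusted p = 0.0346). ATP2A2, the calcium pump of slow fibres, changed by -1.85 from 4757 to 1339 CPM (SE 0.24, adjusted p = 0.026), and ACTA1, skeletal muscle actin, by -2.35 from 2382 to 447 CPM (SE 0.29, adjusted p = 0.026). In all, 103 of 10588 genes changed, 37 up and 66 down. The other largest rises that moved the same way in 4 of 4 pairs were PNPLA3 at 5.92, KCNJ3 (a potassium channel) at 3.88, TTC39B at 2.76, KCNN3 at 2.51, CDC14A at 2.42, STS at 2.41, LONRF3 at 2.35, AKR1C2 at 2.10 and ADAMTS1 at 2.03. The largest falls were DNAH3 at -4.65, LRRC3B at -4.34, PARP15 at -3.54, TNXB (a matrix protein) at -3.20, PPP1R1C at -3.07, RNF150 at -3.02, MMP2 (a matrix protease) at -2.97, GADD45G at -2.93, COLQ at -2.87, STEAP1B at -2.85, PID1 at -2.77 and CLSTN2 at -2.67. MYH7, the slow myosin, was at -2.16 (adjusted p = 0.193) and MYH2 at -2.07 (adjusted p = 0.269), and neither passed. CHRNG at 1.86, MUSK at 0.19, NCAM1 at -0.46, MYOG at 1.00, MYH3 at 0.83, MYH1 at -0.48, FBXO32 at 0.61, TRIM63 at -0.48, PPARGC1A at -0.70, PDK4 at -0.42 and DMD at 0.05 did not pass either. In injured libraries, type II nuclei held more of every named rising gene than type I nuclei except KCNJ3 and AKR1C2, such as PNPLA3 at 126 against 57.2 and CHRND at 89.8 against 47.5 CPM, scaled to the plain class total. In non-injured libraries they held more LRRC3B, at 145 against 40.6, RNF150, at 401 against 260, GADD45G and STEAP1B. Free RNA from type II nuclei was therefore not separated from the type I values of these genes. In non-injured libraries DNAH3, PPP1R1C, COLQ and CLSTN2 were at 84.2, 120, 157 and 115 CPM in type I nuclei. They were at 3.47, 1.33, 36.0 and 9.37 CPM in type II nuclei, which argues against free RNA of type II nuclei as the main source of their falls. On the same scale, TNXB was at 19.2 and 1.74 CPM in type I nuclei and at 2502 and 588 CPM in fibro-adipogenic nuclei, where it fell as well. MMP2 was at 110 and 31.2 CPM in type I and at 282 and 108 CPM in fibro-adipogenic nuclei, where it did not pass (adjusted p = 0.353). In type II nuclei TNXB was at 18.8 and 2.79 CPM and MMP2 at 3.13 and 1.25 CPM. Free RNA of fibro-adipogenic nuclei was not separated from the TNXB values. Such RNA would reach both fibre types, so the low MMP2 level in type II nuclei argues against it as the main source of MMP2 in type I nuclei. Leaving out replicate 1 or replicate 4 gave 0 genes by edgeR, with 917 and 1107 at an unadjusted p under 0.05, while leaving out replicate 2 gave 242. With no replicate block 2 genes were called, and DESeq2 on all replicates gave 401. Camera called 16 of 34 lists, 2 up and 14 down, with a lowest adjusted p = 0.558 with an estimated correlation, and fry called 0 (lowest adjusted p = 0.137). Denervation response genes rose in 4 of 18 members (8 up and 1 down adjusted over the list alone; adjusted p = 1.51e-06), interferon genes in 0 of 8 (2 up adjusted over the list alone; adjusted p = 0.0441), and slow sarcomere genes fell in 1 of 11 (7 adjusted over the list alone; median -1.71, adjusted p = 6.89e-08).

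A test of the interaction asked which changes differed between the fibre types. SMTNL1 (ENSG00000214872, chromosome 11, 57542641 to 57550274), a smoothelin-like protein of fast fibres, was at -1.95 in type I and -4.21 in type II nuclei, a difference of 2.33. The ACTN3 change was more positive in type I than in type II nuclei by 3.94, and TTC39B, a gene of cholesterol handling, was at 2.76 against 1.15, a difference of 1.47. ATP2A2 was at -1.85 in type I against -0.19 in type II nuclei, a difference of -1.63. In all, 40 of 12351 genes differed, 32 with the more positive change in type I nuclei and 8 with the more negative. All of the 40 but ATP2A2 and TTC39B had the larger change in size in type II nuclei. For most of the 32, more positive meant a smaller fall in type I nuclei. Among others, named after their values were seen, were KY (a protease of the Z-disc) at 2.37, AQP4 (a water channel) at 3.25, SPOCK1 at 3.07, IGFN1 at -2.18 and SDC4 at -1.51. With no replicate block edgeR called 0 genes, with 205 at an unadjusted p under 0.05, and with the block DESeq2 called 89. Leaving out replicate 1, 2, 3 or 4 gave 9, 289, 2 and 14 genes.

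All myonuclei pooled were compared to read fibres of both types at once. ANKRD1 rose by 5.31 (adjusted p = 0.0139), RUNX1 by 3.72 (adjusted p = 0.0162), MYOG by 1.46 and GADD45A by 2.12, and PNPLA3 at 3.95, GDNF at 3.09 and KCNJ3 at 2.92 completed the largest rises. ACTN3 at -5.51, SLIT3 (a guidance cue) at -5.02, NREP at -4.00, SCUBE2 at -3.86 and PARP15 at -3.67 were the largest falls, and MYH2 changed by -1.61. In all, 649 of 13974 genes changed, 194 up and 455 down. CHRNA1 at 4.05 (adjusted p = 0.0836), CHRND at 2.21 (adjusted p = 0.0509) and MYH7 at -1.41 (adjusted p = 0.0851) did not pass. Non-injured library 2 stood apart, with CHRNA1 at 218 CPM against 4.75, 25.6 and 0 in libraries 1, 3 and 4, and CHRND at 47.9 against 3.96 to 17.6. Without replicate 2, CHRNA1 at 5.16 and CHRND at 2.74 passed (adjusted p under 0.05 each). The sum of that library included 1141 COL19A1-rich nuclei of no assigned type, which held CHRNA1 at 648 CPM. Leaving out replicate 4 gave 18 genes and replicate 1 gave 295, and these sums mix fibre types whose shares differed between libraries. Camera called 13 of 35 lists, 1 up and 12 down, with a lowest adjusted p = 0.442 with an estimated correlation, and fry called 5 (lowest adjusted p = 0.0461).

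Fibro-adipogenic nuclei were compared to ask how connective tissue responded. FN1 (fibronectin) fell from 838 to 174 CPM, a log2 change of -2.19 (SE 0.27, adjusted p = 0.00199), and COL14A1, a fibril-associated collagen, changed by -2.46 (SE 0.41, adjusted p = 0.00678). NID2, a basement membrane protein, rose by 2.43 and COL5A3, a fibrillar collagen, by 1.91. CD55 and CLU, regulators of complement, changed by -2.88 and -2.55. In all, 322 of 7357 genes changed, 140 up and 182 down. The largest rises that moved the same way in 4 of 4 pairs were ANKRD1 at 5.30, GPM6B at 3.92, DACH1 at 3.86, FGFR4 at 3.72 and LRRC7 at 3.37, and the largest falls CCN3 at -5.88, HSD3B7 at -5.30, ACTN3 at -5.04, KCTD16 at -5.03 and CD70 at -4.58. Leaving out replicate 1 gave 56 genes and replicate 2 gave 193. Among genes tested in both batches, libraries 1 and 2 alone called 172 up and 239 down, and libraries 3 and 4 alone 4 and 0. Of those called in libraries 1 and 2, 89.3% moved the same way in libraries 3 and 4. Injured library 2 held 29 of these nuclei, with 33607 UMIs. At resolution 1.0 these nuclei split, and a smaller cluster, with PRG4, FBN1 and MFAP5 among its leading genes, held 39.1%, 27.5%, 18.7% and 28.2% of them in non-injured and 2.86%, 0%, 4.07% and 4.89% in injured libraries. In the larger cluster alone, an alternative chosen after the data were examined, 157 genes changed, with FN1 at -1.34, COL14A1 at -2.59, NID2 at 1.86, COL5A3 at 1.66 and CD55 at -1.96. CCN3, HSD3B7, KCTD16 and CD70 had no counts in 3 of the 4 injured libraries, so their fitted changes depend on the prior count. Free myofibre RNA predicted 321 CPM of rise for ANKRD1 in these nuclei against 182 CPM observed, before TMM scaling, so its rise here is not read as expression. ACTN3, ACTA1 at -2.26, ATP2A1 at -2.31 and MYH2 at -1.31 are fibre transcripts as well. The free fraction in these nuclei, a median over 20 myofibre transcripts, was 63.2%, 70.7%, 13.8% and 14.1% in the non-injured and 84.8%, 67.3%, 15.5% and 20.2% in the injured libraries. Single genes departed from it. In non-injured library 2 it predicted 120 CPM of ANKRD1 and 208 of ACTN3, with 13.1 and 48.3 observed. In non-injured library 3 it predicted 67.7 CPM of ACTN3, with 113 observed. Clock genes fell in 4 of 11 members, NR1D1 at -2.30, HLF at -1.65, NR1D2 at -1.38 and PER3 at -1.34, with the same count adjusted over the list alone (camera adjusted p = 0.128). Extracellular matrix genes rose in 4 and fell in 7 of 36 members (5 and 14 adjusted over the list alone), with a median of -0.60 (adjusted p = 0.0353, and adjusted p = 0.932 with an estimated correlation). Camera called 8 of 33 lists and fry 0 (lowest adjusted p = 0.408).

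Endothelial and satellite cell nuclei had 3 pairs with enough nuclei. In satellite cell nuclei ANKRD1 rose from 22.3 to 438 CPM, a log2 change of 4.23 (adjusted p = 0.0139), and was the 1 gene of 5593 that changed by edgeR. Free myofibre RNA predicted 583 CPM of rise in these 3 pairs against 369 CPM observed, before TMM scaling, so the rise is not read as expression. Leaving out replicate 1 gave 34 genes and replicate 3 gave 2. In endothelial nuclei edgeR called 0 of 4971 genes, with 275 at an unadjusted p under 0.05 and 16 by DESeq2, and leaving out replicate 3 gave 514 from 2 pairs. There ANKRD1 at 4.55 did not pass (adjusted p = 0.063). Fast sarcomere genes were lower in satellite cell nuclei in 0 of 13 members over all genes and in 10 adjusted over the list alone (median -1.29, adjusted p = 6.27e-12, and adjusted p = 0.651 with an estimated correlation). By the median of 20 myofibre transcripts, free RNA in these nuclei was 61.95% to 90.11% of the myonuclear level in the 3 pairs. These values are therefore not read as expression of satellite cells. Interferon genes in endothelial nuclei had a median of 0.81 with no member past the threshold, also adjusted over the list alone (adjusted p = 0.000131, and adjusted p = 0.68 with an estimated correlation). Camera called 9 of 30 lists in endothelial and 10 of 31 in satellite cell nuclei, and fry 0 in both (lowest adjusted p = 0.195 and 0.28). Mural and macrophage nuclei had 2 pairs with enough nuclei and were not tested for genes.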

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

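The test of nuclei mixed in from an injured biopsy and the values from CPM were chosen only after results were seen; the test of the smaller fibro-adipogenic cluster was added late, before its own result was seen, and the other tests were chosen before. Of 208 groups of 4 libraries, 22 had a library far from the rest by Dixon's gap ratio. Chance flags about 1 in 20 groups if values are independent and normally distributed. CPM need not be so distributed and the groups share libraries, so no excess over chance is read from the count.

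In type II nuclei of non-injured library 2, ANKRD1 was at 69.22 CPM with the others at 4.31 to 11.5, CHRNG at 23.6 with 0.786 to 2.96, NCAM1 at 470.2 with 16.5 to 80.6, and COL19A1 at 21.26 with 1.44 to 3.59. DACH1 in fibro-adipogenic nuclei of that library was at 43.32 CPM with the others at 6.91 to 11.8, and TTC39B in its type I nuclei at 24.21 with 5.70 to 8.04. MIR503HG in type II nuclei was high in non-injured library 4, at 1.437 CPM with 0.157 to 0.375, and in injured library 3, at 119.4 with 15.1 to 25.5. Type I nuclei made up 27.61% of typed fibre nuclei in non-injured library 1, with 17.9% to 19.1% in the others. In type I nuclei of injured library 2, PNPLA3 was at 184.6 CPM with 7.35 to 11.9, KCNN3 at 488.5 with 105.8 to 121, AKR1C2 at 73.09 with 14.8 to 22.4, and DMD lowest at 8520 with 11640 to 12180. In type I nuclei of injured library 3, MYH2 was at 809.0 CPM with 69.2 to 183 and MYH1 at 720.8 with 33.9 to 141.5. MMP2 in type I nuclei of injured library 4 was at 112.9 CPM with 0.550 to 6.01 in the others. In type II nuclei, RUNX1 was lowest in injured library 4, at 937.9 CPM with 2130 to 2307, and GXYLT2 lowest in injured library 1, at 6.741 with 45.0 to 49.7. In fibro-adipogenic nuclei, CCN3 was at 28.81 CPM in injured library 2, and HSD3B7 at 3.892, KCTD16 at 3.892 and CD70 at 7.784 in injured library 4, with 0 in the other injured libraries. The change differed between type I and type II nuclei by the interaction test in 40 genes, among them ACTN3 by 3.94, SMTNL1 by 2.326 and TTC39B by 1.473.

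ANKRD1 rose in fibro-adipogenic nuclei of injured biopsies. Free myofibre RNA predicted 176.7% of the observed rise, so it may be the whole source. Of the other genes changed there, 12.15% had a predicted difference of at least 50% of the observed one, which argues against free RNA as the source of most of them. Fewer nuclei of the smaller fibro-adipogenic cluster at resolution 1.0 were tested as the whole cause. Over 268 of these 321 genes the mean signed change inside the larger cluster was 85.54% of that in the class. The other 53 had too few counts there; from CPM, all 321 gave 84.4% and these 53 gave 76.7%. These percents may be too high, since the genes were called on sums that include the larger cluster. It held 93.5% to 100% of the class in injured and 59.5% to 80.3% in non-injured libraries. Of the 268, 148 still passed in the larger cluster alone, and for these the smaller cluster is argued against as the whole cause. A part from the mix of nuclei, a finer mix inside the larger cluster and a response of connective tissue to injury stay open.

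Of 1366 COL19A1-rich myonuclei, 1141 came from non-injured library 2, where they were 24.3% of nuclei (95% CI 23.1 to 25.6). Non-injured libraries 1, 3 and 4 held 21, 27 and 0, and injured libraries 1 to 4 held 20, 33, 71 and 53. A swap of the labels of that pair is argued against, since 95.73% of genes called in type II nuclei from the other 3 pairs moved the same way in this pair. A wrongly labelled injured biopsy is argued against, since this pair's mean signed change was 96.41% of that of the others, and doublets with satellite cells, since PAX7 was at 0.8582% of its level in those cells. Injured libraries held the cluster at no more than 2.144%, which argues against nuclei mixed in from them. Local damage or an end region of fibres in that biopsy may be a source, and no biological explanation was tested.

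More genes changed in type II than in type I myonuclei, 1415 against 103. Depth is argued against as the cause: type II sums thinned to type I totals still gave a median of 1177 genes over 5 draws. Whether type I changes are smaller cannot be told apart from equal changes, because their mean signed size was 86.53% of the type II size for genes called in 2 of the replicates and 42.4% for genes called in the other 2. The genes of the interaction test, a small set picked for differing, changed more in type II nuclei, apart from ATP2A2 and TTC39B. Free RNA and the spread between type I sums stay open.

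Splits that part every pair were too few for a share under 0.05, 8 in classes with 4 pairs and 4 in classes with 3. The real split gave 649, 103, 1415 and 322 genes in all myonuclei, type I, type II and fibro-adipogenic nuclei, each reached by 1 of the 8 splits, the real one, with 0 as the highest other. Endothelial nuclei gave 0 genes in 4 of 4 splits, satellite cell nuclei 1 gene with 0 as the highest other, and the interaction 40 genes with 1 as the highest other. For gene lists the real split gave 13, 16, 13 and 8 in those first classes, with 15, 15, 14 and 8 as the highest other and with 2, 1, 2 and 3 splits giving as many. Endothelial nuclei gave 9 lists with 9 as the highest other in 2 splits, and satellite cell nuclei 10 with 5 in 1 split. The split with 15 and 14 lists exchanged the labels of replicate 4, so camera's calls at its preset correlation also arise without the full contrast. The 24 splits that part only 2 pairs gave 0 genes in all myonuclei and in type II nuclei. In every split but the real one, a real difference adds to the residual spread. Their low gene counts therefore say little about chance.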

How the results depend on the processing

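Alternatives changed 1 choice each, except that the stricter filter moved both limits on nuclei and DESeq2 both the model and the genes given an adjusted p. Direction was compared only where the reported or the alternative value passed its threshold. No named gene reversed: of 1701 alternatives 1458 kept direction and side of the threshold, 192 fell short and 51 newly passed. The lack of reversals shows little. Genes named as largest rises or falls were chosen for moving the same way in every pair, so leaving out replicates could hardly reverse them. None of 156 alternatives of the shares and quality measures passed an adjusted threshold, which shows little: the sign-flip test cannot go below 0.125, and fewer libraries cannot pass. Unadjusted, the macrophage share gave an exact permutation p = 0.0286 with doublets kept, without integration and at resolution 1.0. That is the smallest p of the full test, which adjustment over the family can hardly leave under 0.05. Of 175 counts of genes or lists, 112 were within 1.5 times the reported count. For the others the cause was not tested.

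With no replicate block, genes changed were 152 in all myonuclei, 2 in type I, 817 in type II and 193 in fibro-adipogenic nuclei, 0 in satellite cell nuclei and 0 in the interaction, and lists in fibro-adipogenic nuclei 5. With no low-count filter they were 1842, 848, 2211, 597, 74 in endothelial, 129 in satellite cell nuclei and 426 in the interaction, with 5 lists in fibro-adipogenic and 18 in endothelial nuclei. With DESeq2 they were 1367 in all myonuclei, 401 in type I, 16 in endothelial and 26 in satellite cell nuclei and 89 in the interaction; with DESeq2's size factors 4 in satellite cell nuclei. Replicates 1 and 2 alone gave 19 in all myonuclei, 0 in type I, 506 in fibro-adipogenic, 514 in endothelial and 2 in satellite cell nuclei. Replicates 3 and 4 alone gave 10 lists in type I and 4 genes in fibro-adipogenic nuclei. Without integration there were 222 in type I, 2 in endothelial and 18 in satellite cell nuclei and 390 in the interaction. With class sums thinned to equal totals there were 58 in type I, 58 in fibro-adipogenic nuclei with 0 lists, 5 lists in endothelial nuclei, 31 genes in satellite cell nuclei and 15 in the interaction. The stricter filter gave 160 in endothelial and 16 in satellite cell nuclei and 5 lists in fibro-adipogenic nuclei; keeping doublets gave 14 and 24 genes in endothelial and satellite cell nuclei. Without haemoglobin-rich clusters, an alternative chosen after the data were examined, there were 601 in all myonuclei, 90 in type I, 1380 in type II and 43 in the interaction. The larger fibro-adipogenic cluster alone, chosen likewise, gave 157 genes and 2 lists.

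Leaving out each replicate gave 18 to 546 genes in all myonuclei, 0 to 242 in type I, 732 to 1124 in type II, 56 to 430 in fibro-adipogenic nuclei with 2 to 7 lists, 0 to 514 in endothelial and 1 to 34 in satellite cell nuclei, and 2 to 289 in the interaction. Removing replicate 1 gave 295 in all myonuclei, 0 in type I, 56 in fibro-adipogenic and 34 in satellite cell nuclei and 9 in the interaction, with 5 lists in fibro-adipogenic nuclei. Removing replicate 2 gave 242 in type I and 193 in fibro-adipogenic nuclei and 289 in the interaction. Removing replicate 3 gave 514 in endothelial and 2 in satellite cell nuclei and 2 in the interaction. Removing replicate 4 gave 18 in all myonuclei, 0 in type I, 732 in type II and 14 in the interaction, with 2 lists in fibro-adipogenic nuclei. Where edgeR called 0 genes, 1213 were at an unadjusted p under 0.05 in type I nuclei with replicates 1 and 2 alone, 917 and 1107 without replicate 1 and 4, 300 in satellite cell nuclei and 205 in the interaction with no replicate block, and 83 in endothelial nuclei without replicate 1 and also without replicate 2. Resolution 1.0 could be given for shares only, and mural and macrophage genes were not tested, since the design asked for 3 pairs. The simulated fits recovered 5.7% of changes of 1 on the log2 scale in endothelial nuclei and 2% in the interaction, and what depth limits there was not separated from pairs and spread.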

Other observations

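COL19A1-rich myonuclei were read in non-injured library 2, where 64.9% of 8395 genes were higher in them than in type II nuclei. They held COL19A1 at 1223 CPM, against 19.3 in type II nuclei of the same library. The receptor genes CHRNA1 at 648 against 38.9 and CHRNG at 382 against 21.5, the synaptic kinase MUSK at 237 against 16.1 and RUNX1 at 2148 against 162 were high in them. So were EDA2R, a receptor of the muscle wasting response, at 98.9 against 2.73, FST (follistatin) at 202 against 7.93, the growth arrest gene CDKN1A at 81.6 against 4.69, the perinatal myosin MYH8 at 71.1 against 7.50 and ANKRD1 at 443 against 63.0. ACTN3 at 27.6 against 483, HDAC9 at 29.6 against 363 and MYH1 at 1127 against 3312 were low. These are single values of 1 library, without a replicate, and these genes were chosen after their values were seen.

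The hypothesis was that these nuclei carry part of the change seen in injured biopsies. Of genes called in type II nuclei from the other 3 pairs, 89.17% differed in the same direction between the COL19A1-rich and the type II nuclei of non-injured library 2. That was 90.5% of 367 rising and 88.4% of 639 falling genes, while 64.9% of all 8395 genes were higher in these nuclei. Across genes, which are not independent replicates, the correlation was 0.597. A state shared by these nuclei and the injured fibres may therefore exist in a biopsy labelled non-injured, and the injured change itself was not tested in them.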
